A study of Homo sapiens with 4 samples.

How the data were processed

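The series measured gene expression in HEK293 cells, a human embryonic kidney line transformed with adenovirus DNA, that carry an inducible WTX gene. WTX is the tumour suppressor now named AMER1. Total RNA from 2 clones, F5 and F18, was labelled with a 3' kit and hybridised to 4 Affymetrix arrays. Each clone had 1 array of cells treated with 1 μg/ml doxycycline for 12 hr and 1 array of untreated cells, so each group had 2 arrays. The labels do not say whether arrays came from separate cultures or days. The p-values set a change against the disagreement of the 2 clones' changes on these 4 arrays, pooled mostly over genes of like brightness. No clone had 2 arrays of the same treatment. The p-values thus cannot separate the spread between cultures from differing responses of the clones. No batch or scan information was used here.

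The deposited values are linear intensity values, 1 per probe set, made with GCOS, Affymetrix's scanner software, per the submitters' processing notes. The version, the algorithm and its parameters are not given in the sources used here. From the values themselves, each array was scaled globally: the mean without the lowest and highest 2% lay at 150 on every array to the nearest whole number. The file held 54675 probe sets, 62 of them controls. Under the platform annotation 41091 probe sets had 1 gene symbol, 1801 had several and 11721 had none. Symbols of 41037 probe sets were looked up by gene ID in the RefSeq table of assembly GRCh38.p14, which was used for names and gene spans only. Probe positions were not analysed here, so no coordinates are given.

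For the analysis a pseudocount of 14.7, the 25th percentile of all deposited values, was added and log2 was taken. Fold changes are therefore on the log2(value + pseudocount) scale, which understates the change of low genes. No further normalization was applied. Each gene was represented by the probe set with the highest mean among those with exactly 1 symbol. Of 19775 such genes, the 12840 whose mean was at or above the median of all probe sets (5.95 on the log2 scale) were tested. limma 3.58.1 in R 4.3.3 fitted doxycycline and clone together, with clone as a block, and eBayes used an intensity trend. The design left 1 residual degree of freedom per gene, and the trend contributed 35.9 prior degrees of freedom, so the errors rest mostly on spread shared across genes of like brightness. All adjusted p-values are limma's with Benjamini-Hochberg adjustment over the tested genes, two-sided, and a gene was called at an adjusted p under 0.05. The pairing comes from the clone named in the labels: both arrays of a clone come from the same cell line.

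Gene lists were tested with camera at a preset inter-gene correlation of 0.01, adjusted over 37 lists, again with estimated correlations, and with fry. With 1 residual degree of freedom the variant with estimated correlations has little power, so a list that fails it is not thereby shown to be unchanged. Conversely, p-values at the preset correlation are too small where the genes of a list vary together more than that. Estimated correlations were -0.03 for p53 targets, 0.11 for immediate-early genes and 0.56 for cytosolic ribosomal proteins, and they too rest on 1 residual degree of freedom. The lists covered p53, beta-catenin, NRF2, growth factor, stress, cell cycle and metabolic genes, and markers of other cell types. All 877 list entries matched a current symbol. For the lists called, medians were set against those of 10000 random lists of the same size matched on mean signal. The lists, the limma test, camera at the preset correlation and the rule for named genes were fixed before the data were examined. The brightness-matched lists were added as a test after the results had been seen. The rule names AMER1 first. For doxycycline it takes the 12 higher and 12 lower genes with the largest smaller change of the 2 clones, called genes first, and for the clones the 8 higher and 8 lower in the same way. It takes up to 4 members of each list described, and CDKN1A, MDM2, AXIN2, NQO1, MYC and CCND1 by name. Any other gene named was chosen after its values were seen.

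The procedure was tested on simulated data with noise drawn from the fitted trend and 200 of 12840 genes changed. For doxycycline it recovered 31.3% of 1.5-fold changes, 83.6% of 2-fold changes and 95.5% of 3-fold changes, with 7 false calls among 147. For the clones the shares were 41.8%, 79.1% and 95.5%, with 3 false calls among 147. camera called 1 list although no list had been changed. The simulation used the noise model that the fit assumes, so it does not test that model.

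Alternatives changed the pseudocount, the filter, the scaling between arrays, the eBayes prior, the choice of probe sets, the block and the arrays included. Cyclic loess between arrays and a test of gene families by symbol stem were added after seeing the data. Figures were drawn with matplotlib 3.10.9. The number of arrays limits the precision of every value.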

Results

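Expression was measured on 4 arrays of HEK293 cells with inducible WTX (AMER1), a tumour suppressor inactivated in part of Wilms tumours. Clones F5 and F18 each gave 1 array after 12 hr in 1 μg/ml doxycycline and 1 array of untreated cells. The median signal was 49.2 and 51.4 on the doxycycline arrays of F5 and F18, and 50.1 and 50.5 on the untreated arrays. Across probe sets the log2 signals of any pair of arrays correlated with a Pearson r between 0.908 and 0.914. The ratio of the 5' to the 3' control probe set of GAPDH was 0.904 and 1.04 on the doxycycline arrays of F5 and F18, and 1.03 and 1.04 on the untreated arrays. The same ratio of ACTB was 0.636 and 0.847 with doxycycline, and 0.892 and 0.780 without. The median signal of the spike-in control probe sets was 1108 and 1393 with doxycycline, and 1418 and 1393 without. The doxycycline F5 array was thus the lowest in both ratios and in the spike-in signal. The 99th percentile of the signal was lower on the doxycycline arrays, at 3171 and 3106, than on the untreated arrays, at 3520 and 3571, so the brightest probe sets read lower with doxycycline in both clones.

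AMER1, the gene to be induced, was read by 1 probe set named for it. Its signal in F5 was 13.3 with doxycycline and 51.1 without, and in F18 it was 18.2 with doxycycline and 11.4 without. The log2 change was -0.45 ± 0.49 (SE), with -1.24 in F5 and 0.33 in F18. The probe set lay at the 31.0th percentile of mean signal, below the filter, where the changes of 1000 probe sets of like brightness had an SD of 0.77 in F5 and 0.78 in F18. Which part of the transcript it reads, and whether the transgene holds that part, was not analysed here, so the arrays neither show nor exclude the induction of WTX.

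The comparison the series was made for asks which genes differ after 12 hr of induction. Doxycycline arrays had 427 called genes among 12840, 263 higher and 164 lower. Of these, 426 moved the same way in both clones. The call largely fixes that, as it needs an averaged change well above the usual disagreement of the clones. Agreement over all tested genes is given below. The change was at least 1.5-fold in both clones for 206 of the called genes. FOSL1, a FOS-family subunit of the AP-1 transcription factor, rose the most, by 2.63 ± 0.34 (SE) on the log2 scale (adjusted p = 3.99e-06), from signals of 22.5 in F5 and 14.9 in F18 to 196 and 185. CDKN1A, which encodes the cell cycle inhibitor p21, rose by 1.78 ± 0.16 (adjusted p = 3.32e-09), from 480 and 632 to 2076 and 1787. RHOB, a small GTPase, rose by 1.56 ± 0.15 (adjusted p = 6.32e-09), from 910 and 836 to 2745 and 2473. The stress-responsive kinase PLK3 rose by 1.97 ± 0.31, the alkaline ceramidase ACER2 by 1.86 ± 0.42, and the fatty acid binding protein FABP2 by 2.05 ± 0.40. Their untreated signals in F5 and F18 were low: 22.9 and 47.4 for PLK3, 14.7 and 21.1 for ACER2, and 19.9 and 17.2 for FABP2. These lay below the median of their arrays. The phospholipase PLCD1 (1.73 ± 0.34), the TNF receptor family member RELT (1.66 ± 0.32) and the translational regulator CPEB2 (1.68 ± 0.21) rose as well. PLCD1 and RELT also lay below the array medians on both untreated arrays, as did MAFG on that of F18 (18.2). So did the small MAF protein MAFG (1.87 ± 0.31), the macrophage growth factor CSF1 (1.63 ± 0.22) and the death domain protein PIDD1 (1.43 ± 0.28). Other probe sets of PLK3 (0.59 and 0.33), CPEB2 (0.30), CSF1 (0.68) and RHOB (1.10) gave smaller changes in the same direction, and that of PIDD1 a larger one (2.16).

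Among the 12 named genes that fell were the pseudogenes GUSBP11 (-1.69 ± 0.30) and C22orf46P (-1.83 ± 0.35), read at low signals with doxycycline. The chaperone cofactor TSACC (-1.52 ± 0.37) and the lymphotoxin beta receptor LTBR (-1.41 ± 0.37) also fell to low signals. Untreated means of these genes lay between 112 and 166, and doxycycline means between 29.4 and 41.4. The other probe set of GUSBP11 changed by -0.25. The potassium channel KCNA6 (-1.40 ± 0.37), the sodium-potassium-chloride cotransporter SLC12A1 (-1.44 ± 0.37) and the copine CPNE9 (-1.45 ± 0.42) fell from untreated means between 89.6 and 117. CLN6, an endoplasmic reticulum membrane protein, fell by 1.45 on its brightest probe set, while its other probe sets changed by -0.13, -0.40 and -0.20. At higher signals the nuclear envelope phosphatase CTDNEP1 fell in F5 from 1382 to 660 and in F18 from 1390 to 668 (-1.04 ± 0.15, adjusted p = 3.02e-05). The small GTPase RAB13 (-0.93 ± 0.15), the small nucleolar RNA host gene SNHG19 (-0.88 ± 0.15) and SNRPD2, a core protein of spliceosomal snRNPs (-0.85 ± 0.14), fell too. Of the genes named in advance, MDM2 rose, and MYC (0.48 ± 0.17, adjusted p = 0.0991), AXIN2 (0.28 ± 0.24), NQO1 (0.38 ± 0.28) and CCND1 (0.13 ± 0.18) did not pass.

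The count of called genes rests on the model. It was 0 without the intensity trend (1542 genes at an unadjusted p under 0.05 there, against 2202 with it), 31 without the filter on low signal, 110 without the clone as a replicate block and 148 without probe sets ending in _x_at or _s_at. With arrays centred on their median the split turned, to 200 higher and 345 lower, and in fits without the block the count ran from 161 without the untreated F5 array and 211 without the untreated F18 array to 1615 without the doxycycline F18 array. The split turned there too, to 742 higher and 873 lower, and without the doxycycline F5 array to 216 higher and 274 lower.

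**Figure D1:**
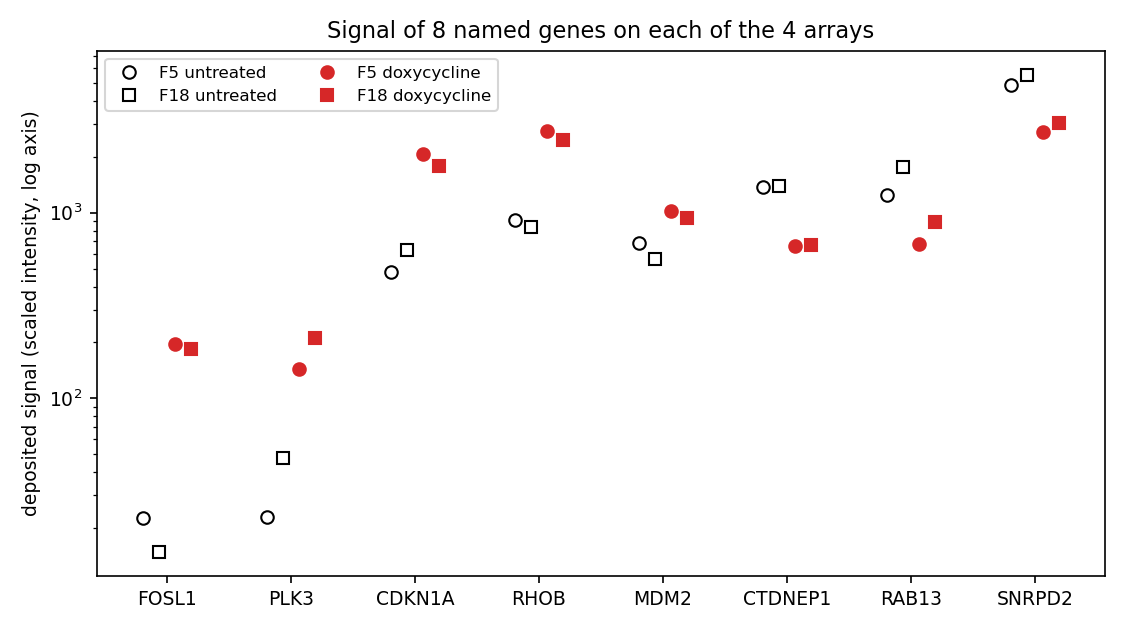
Deposited signal (scaled intensity, log axis) of 8 called genes on each of the 4 arrays; open symbols are untreated, filled symbols doxycycline, circles F5 and squares F18. Both doxycycline arrays lie above both untreated arrays for FOSL1, PLK3, CDKN1A, RHOB and MDM2, and below them for CTDNEP1, RAB13 and SNRPD2, where the signal of SNRPD2 fell from 4882 and 5549 to 2724 and 3039.

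Many targets of the tumour suppressor p53 rose. Of 25 tested, 16 rose and 0 fell, and 20 rose when adjusted over the list alone. PLK3 and CDKN1A were joined by SESN2, a stress-induced regulator of mTORC1 (1.65 ± 0.17, adjusted p = 6.53e-08), and TNFRSF10B, the death receptor for TRAIL (1.36 ± 0.16, adjusted p = 4.14e-07). MDM2, the ubiquitin ligase that degrades p53, rose by 0.64 ± 0.16 (adjusted p = 0.0158), and its other 5 probe sets changed by 0.46 to 1.31. The median change of the list was 0.83, with 0.81 in F5 and 0.84 in F18, and 22 members were higher in both clones. camera called the list (adjusted p = 3.71e-27), and the adjusted p was 0.676 with an estimated correlation, where 0 of 37 lists were called. The brightness-matched random lists had medians between -0.12 and 0.15.

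Part of the immediate-early genes, which growth factors and stress induce without new protein synthesis, rose as well. Of 23 tested, 11 rose and 0 fell, 19 rose when adjusted over the list alone, and the median was 0.76, with 0.85 in F5 and 0.50 in F18. Besides FOSL1, the AP-1 subunit JUN rose by 1.43 ± 0.16 (adjusted p = 1.78e-07), the stress-induced transcription factor ATF3 by 1.19 ± 0.16 and the ERK phosphatase DUSP5 by 1.14 ± 0.17. camera gave an adjusted p of 4.43e-18, and 0.676 with an estimated correlation. This list and the p53 list shared 0 tested members. Of 16 ERK feedback genes 4 rose, 5 when adjusted over the list alone: FOSL1, DUSP5, the ephrin receptor EPHA2 (1.04 ± 0.22) and IER3 (0.87 ± 0.21). FOSL1, DUSP5 and IER3 are also on the immediate-early list. The feedback inhibitor SPRED1 did not pass (1.00 ± 0.34, adjusted p = 0.0926). Their median was 0.41 (camera adjusted p = 4.98e-05, and 0.676 with an estimated correlation).

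**Figure D2:**
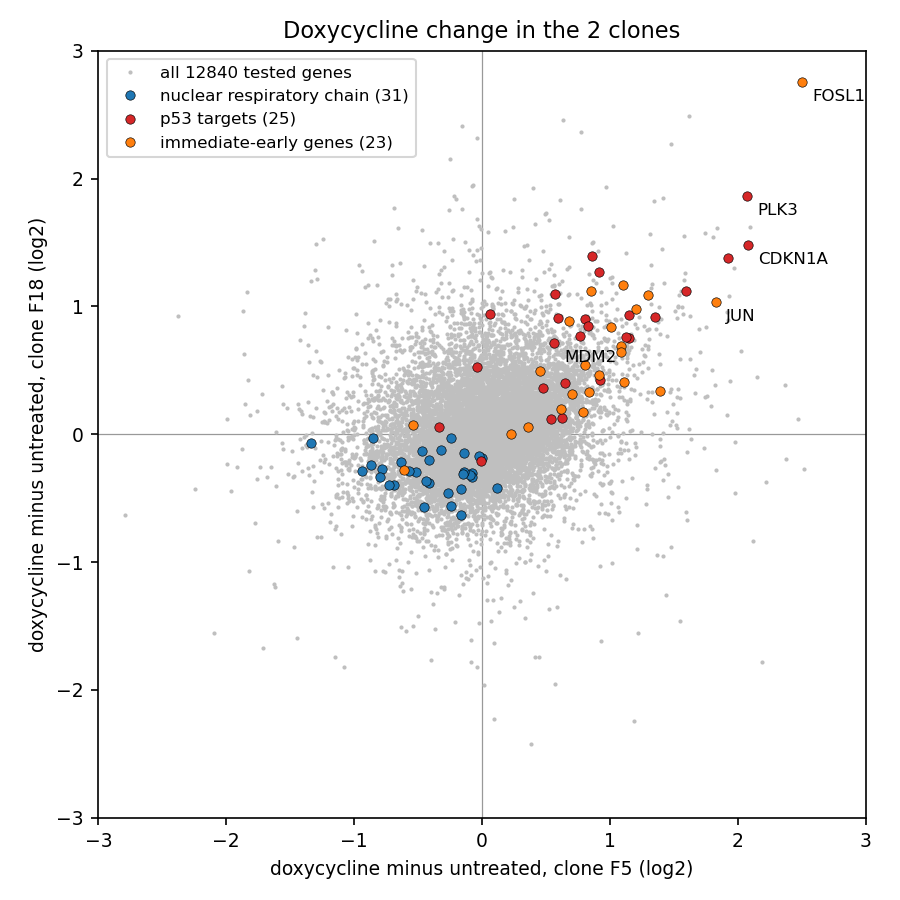
Doxycycline minus untreated change (log2) in clone F5 (x axis) against clone F18 (y axis), 1 point per tested gene, with 25 p53 targets, 23 immediate-early genes and 31 nuclear genes of the respiratory chain coloured. Of the p53 targets 22 lie above 0 on both axes, with CDKN1A at 2.08 in F5 and 1.48 in F18.

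Of 30 genes of the G1/S transition 4 rose, 6 when adjusted over the list alone. They were the E cyclins CCNE2 (1.06 ± 0.18) and CCNE1 (0.59 ± 0.16), the transcription factor E2F2 (0.82 ± 0.18) and the replication licensing factor CDC6 (0.62 ± 0.16). The median was 0.10 (camera adjusted p = 0.00760, and 0.676 with an estimated correlation), and the call ended without the intensity trend (adjusted p = 0.0757). The median was 0.21 after quantile normalization, 0.20 after cyclic loess and 0.02 with arrays centred. Of 16 heat shock genes 5 rose, and 7 rose and 1 fell when adjusted over the list alone. The 5 were the cochaperones BAG3 (0.88 ± 0.16) and DNAJB1 (0.90 ± 0.15) and the chaperones HSPA6 (1.00 ± 0.28), HSPH1 (0.63 ± 0.15) and HSPA4L (0.64, named after its value was seen). Their median was 0.015, their mean 0.24 and the camera adjusted p 0.0294 (0.676 with an estimated correlation). The median lay inside the range of brightness-matched lists, -0.26 to 0.05, while the clone medians were 0.12 in F5 (percentile 97.3) and 0.08 in F18 (percentile 99.5). The averaged median turned to -0.06 with arrays centred on their median and was 0.22 after quantile normalization and 0.23 after cyclic loess, and the call ended under 4 alternatives, the fit without the block among them (adjusted p = 0.0681). Of 14 YAP/TAZ targets 1 rose, CCN1, a matricellular protein (0.79 ± 0.22) that is also on the immediate-early list, likewise 1 over the list alone, and 11 were higher in both clones. Values of AMOTL2 (0.61 ± 0.29), LATS2 (0.41 ± 0.19) and CRIM1 (0.44 ± 0.20) did not pass; the list's median was 0.30 (camera adjusted p = 0.010, and 0.676 with an estimated correlation). Of 21 beta-catenin targets 2 rose, 3 over the list alone: LGR5, a receptor for R-spondins (1.08 ± 0.20), and BAMBI, a decoy receptor of TGF-beta signalling (0.58 ± 0.15). TNFRSF19 (-0.66 ± 0.32) and JAG1 (0.44 ± 0.22) did not pass. The median was 0.20, with 0.25 in F5 and 0.07 in F18 (camera adjusted p = 0.0294, and 0.676 with an estimated correlation), and the call ended without the filter (adjusted p = 0.0582), without the trend (0.0705) and without _x_at and _s_at probe sets (0.157).

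Some nuclear genes of the mitochondrial respiratory chain fell. Of 31 tested, 7 fell and 0 rose, 17 fell when adjusted over the list alone, and 29 were lower in both clones. The complex I subunits NDUFB3 (-0.56 ± 0.15, adjusted p = 0.0292) and NDUFB10 (-0.54 ± 0.15, adjusted p = 0.0288) fell. The ATP synthase subunit ATP5MC1 (-0.51 ± 0.15, adjusted p = 0.0521) and the cytochrome oxidase subunit COX7A2 (-0.40 ± 0.14, adjusted p = 0.117) did not pass. The median was -0.40, with -0.41 in F5 and -0.30 in F18 (camera adjusted p = 4.67e-14, and 0.676 with an estimated correlation), and it was -0.21 after quantile normalization and -0.23 after cyclic loess, where the call held. Of 25 cytosolic ribosomal protein genes 3 fell, 5 over the list alone: RPL14 (-0.50 ± 0.14), RPL35 (-0.53 ± 0.14) and RPL8 (-0.54 ± 0.15), with RPL12 (-0.48 ± 0.15) not passing. Their median was -0.26, with -0.35 in F5 and -0.17 in F18 (camera adjusted p = 2.11e-09, and 0.676 with an estimated correlation), but -0.03 after quantile normalization and 0.03 after cyclic loess, where the call ended (adjusted p = 0.0510 and 0.887). The brightest 1% of tested genes, 129 genes, had a median change of -0.29 in F5 and -0.17 in F18. Ribosomal protein genes such as RPL7 and RPLP1 are among them, so they are not an independent reference for that list.

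**Figure D3:**
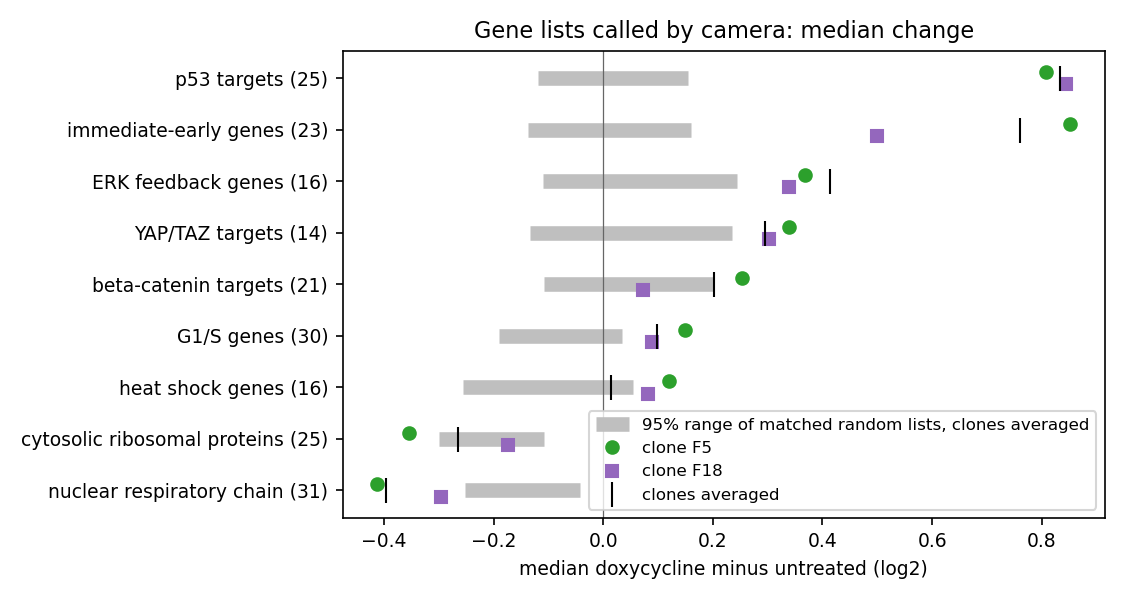
Median doxycycline minus untreated change (log2) of the 9 gene lists called by camera, with the number of tested genes in brackets; circles are F5, squares F18, ticks the clones averaged, and grey bars the 95% range of random lists matched on mean signal. The p53 targets lie at 0.81 and 0.84, outside their grey bar, while the averaged medians of the ribosomal proteins (-0.26) and the heat shock genes (0.015) lie inside theirs. That of the beta-catenin targets (0.20) lies at the upper end of its bar.

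The other 28 lists did not pass, with camera adjusted p from 0.0553 to 0.988. NRF2 targets, antioxidant genes, went both ways, with 4 higher and 3 lower of 21 (median -0.03). SRXN1 (1.09 ± 0.16), GCLM (0.97 ± 0.16), HMOX1 (0.93 ± 0.19) and SLC7A11 (0.67 ± 0.20) rose, and FTL, TKT and TALDO1, named after their values were seen, fell. Of 30 genes of the amino acid response 5 rose (median 0.03, and -0.04 with arrays centred), SESN2, ATF3 and SLC7A11 as well as DDIT4 and CEBPB, the last pair named after their values were seen. Of 13 NF-kappaB targets NFKBIE (1.05 ± 0.29) and IER3 rose and NFKBIA (-0.86 ± 0.19) fell (median 0.15). In 17 TGF-beta targets BAMBI and ID4 (0.58 ± 0.15) rose (median -0.11). Apoptosis regulators had a median of 0.14 with 1 called gene, PMAIP1 (0.57 ± 0.14). The neuronal list had a median near zero with 2 called genes, NEFL (1.31 ± 0.15) and ENO2 (0.82 ± 0.22). With 1 gene each, TFRC rose among reference genes (median -0.23, and 0.05 after cyclic loess), GAS1 among Hedgehog targets (0.19) and NRARP among Notch genes (0.17). GAS1 itself was 0.58 on its _s_at probe set and -0.99 on another. Likewise with 1 gene each, CEBPA rose among mesenchymal genes (0.04, and -0.04 with arrays centred) and DNAJB9 among endoplasmic reticulum chaperones (0.01, and -0.07 with arrays centred). In the list of metallothioneins and zinc export (-0.20) the 1 gene that rose was the zinc exporter SLC30A1. Sterol synthesis genes (-0.02, and 0.004 after quantile normalization) had INSIG1 higher and EBP lower, hypoxia and glycolysis genes (-0.03, and 0.03 after cyclic loess) had NDRG1 higher and the aldolase gene ALDOA, named after its value was seen, lower, and the beta-catenin destruction complex (0.09) had RBX1 lower (-0.55 ± 0.15).

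In the remaining lists 0 genes were called, apart from the smooth muscle actin ACTA2 (1.24 ± 0.17, adjusted p = 5.78e-06) among fibroblast markers (median 0.13). The medians were -0.08 for G2/M genes, -0.07 for the mitochondrial translation machinery, -0.22 for histones, 0.18 for genes linked to WT1 and -0.08 for ribosome biogenesis. They were 0.10 for acetyltransferases and deacetylases, 0.08 for kidney progenitor genes and 0.01 for interferon-stimulated genes, which turned to -0.06 with arrays centred. Genes encoded in mitochondrial DNA had a median of -0.10, which turned to 0.09 after quantile normalization. Markers of other cell types had medians of -0.16 (squamous epithelium), 0.08 (blood cells) and 0.04 (endothelium, turning to -0.04 with arrays centred), over 7, 5 and 5 tested genes.

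The changes of the clones were also set against each other. Across 12840 genes the doxycycline change of F5 correlated with that of F18 with a Pearson r of 0.25 and a Spearman rho of 0.28. At least 1.5-fold in both clones, 256 genes were higher in both and 84 lower in both, against 112 that went opposite ways (exact binomial p = 8.96e-28 for 340 against 112, two-sided). Genes are not independent replicates, so that p is too small. The clones share no array in this comparison. Without the filter the counts were 868 and 530, and above the 70th percentile of signal 194 and 22.

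The second factor of the design is the clone. Few genes were called between F18 and F5: 15, with 9 higher and 6 lower, and 663 at an unadjusted p under 0.05. The low count does not show that the clones are alike, as 41.8% of 1.5-fold clone differences were recovered in simulated data. RARA, the retinoic acid receptor alpha, was higher in F18 by 3.34 ± 0.27 on its brightest probe set (adjusted p = 8.98e-11), with signals of 371 and 434 in F18 against 36.1 and 18.6 in F5. Of its other probe sets, the brightest differed by -0.59 ± 0.32 and the next by 1.07 ± 0.46. Also higher were MYL10, a myosin light chain (1.94 ± 0.27, but -0.71 on its other probe set), the transcription factor ATF6B (1.63 ± 0.34) and TCEAL8 (1.33 ± 0.17, signals of 834 and 592 against 289 and 255). LINC02504 (1.77 ± 0.34), COLCA1 (1.00 ± 0.15), the collagen chaperone SERPINH1 (1.05 ± 0.22) and the tubulin pseudogene TUBBP5 (0.96 ± 0.19) completed the 8 named. Lower in F18 were the teneurin TENM1 (-2.45 ± 0.38), DDX11L2 (-2.31 ± 0.42), the pseudouridine phosphatase PUDP (-2.39 ± 0.32), the mitochondrial topoisomerase TOP1MT (-1.90 ± 0.39), the sulfotransferase CHST8 (-1.76 ± 0.36) and the sphingomyelinase SMPD2 (-1.27 ± 0.28). SMPD2 differed by -2.29 in untreated cells but only by -0.25 with doxycycline, and its signal of 45.5 on the untreated F18 array stood apart. Of the 15 called genes, 14 differed at least 1.5-fold under both treatments. C16orf78 (-1.79 ± 0.40, adjusted p = 0.0548) and ACVR2B-AS1 (-1.66 ± 0.39, adjusted p = 0.0649) did not pass. Across genes the F18 minus F5 differences of untreated and of doxycycline cells correlated with a Pearson r of 0.02 and a Spearman rho of -0.03. At least 1.5-fold in both treatments, 144 genes differed the same way and 106 opposite ways (exact binomial p = 0.0191, two-sided, with genes that are not independent). The count of called genes was 0 without the intensity trend (666 at an unadjusted p under 0.05), 1 without the filter and 1 without the treatment term, 2 above the 70th percentile and 48 after quantile normalization; in fits without the treatment term, leaving out the doxycycline F5, untreated F5, doxycycline F18 and untreated F18 arrays gave 48, 95, 4 and 2.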

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

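The tests of brightness and of a single deviating array pair were chosen only after the results were seen. The tests of gene span and of the RARA probe sets, and the look for a control of doxycycline alone, were set down before their results were seen.

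Several values moved in opposite directions in the 2 clones; with 1 array per clone and treatment these differences were not tested. NQO1 changed by -0.10 in F5 and 0.86 in F18, a difference of 0.96. The F18 minus F5 difference of the list medians was 0.13 for endoplasmic reticulum chaperones, 0.25 for genes of mitochondrial DNA, 0.16 for sterol synthesis, 0.20 for mesenchymal genes and 0.31 for interferon-stimulated genes. Among markers of other cell types it was 0.21 for fibroblasts, -0.27 for squamous epithelium, 0.27 for blood cells and 0.47 for endothelium.

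The rise of p53 targets and of immediate-early genes with doxycycline might come from brightness-dependent scaling, from 1 deviating array pair, or from doxycycline itself. The p53 list's median of 0.83 and the immediate-early list's 0.76 lay above the upper ends of the 95% ranges of brightness-matched lists, 0.15 and 0.16, which argues against scaling as the whole cause. In F18 alone the p53 median was 0.84 against a bound of 0.14, and the immediate-early median 0.50 against 0.17, which argues against an effect of the F5 pair alone. The series has 0 arrays of cells given doxycycline without inducible WTX, so doxycycline itself and WTX cannot be told apart, and AMER1's probe set does not settle it. Induction of WTX stays a hypothesis for the rise.

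The lower respiratory chain and ribosomal protein genes could reflect the lower reading of bright or short genes on the doxycycline arrays. For ribosomal proteins both are open: the median of -0.26 lay above the 2.5th percentile of -0.30 of brightness-matched lists, and at the 26.9th percentile of lists matched on brightness and gene span. The clones differed there: against brightness-matched lists the F5 median of -0.35 lay at percentile 1.94 and the F18 median of -0.17 at percentile 64.6. The matched lists were drawn from all tested genes, ribosomal protein genes included, so a shared fall of those genes also lowers the lists. For the respiratory chain the median of -0.40 lay below the bound of -0.25 for brightness and at percentile 0 of lists matched on brightness and span (bound -0.28), which argues against either as the whole cause. The brightness-matched lists themselves had a median of -0.16, so part of the size is shared with other bright genes. An effect of doxycycline on mitochondria and an effect of WTX stay open as untested alternatives.

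The higher RARA signal in F18 might mean more RARA mRNA of every form. The brightest of its other probe sets differed by -0.59 ± 0.32, which argues against this, while the next was higher by 1.07 ± 0.46. Whether the called probe set reads a different transcript or other sequence was not analysed here, and no biological explanation was tested.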

How the results depend on the processing

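Where a cause is not evident from the alternative itself, the cause was not tested. The count of genes called with doxycycline (427) was 575 with the pseudocount of 7.33, 595 with 1, 291 above the 70th percentile, 564 after quantile normalization, 545 with arrays centred, 401 with a robust prior, 327 over all probe sets and 427 after cyclic loess, which was chosen after seeing the data. It was 31 without the filter, 148 without _x_at and _s_at probe sets (fewer genes tested), 110 without the replicate block and 0 without the intensity trend. Of the 263 higher genes quantile normalization kept 257 and loess 242; of the 164 lower genes they kept 135 and 110; the fit without the block kept 86 and 24. Leaving out each array, without the block, gave 161 to 1615; the lone array is then assumed to vary like the others. The highest came without the doxycycline F18 array and the lowest without the untreated F5 array.

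The clone count (15) was 25 and 26 with the smaller pseudocounts, 1 without the filter, 2 above the 70th percentile, 48 after quantile normalization, 0 without the trend, 7 without _x_at and _s_at probe sets, 1 without the treatment term and 25 after loess. Leaving out arrays gave 2 to 95, lowest without untreated F18 and highest without untreated F5. The correlation of the clones' changes (0.25) was 0.22 with a pseudocount of 1, 0.14 without the filter, 0.40 above the 70th percentile, 0.24 after quantile normalization, 0.21 over all probe sets and 0.23 without _x_at and _s_at probe sets. Genes changed in the same direction (340) were 868 without the filter, 194 above the 70th percentile and 611 over all probe sets, and opposite ones (112) were 530, 22 and 243, and 170 with a pseudocount of 1. Lists called (9) numbered 6 to 12 under the other settings, and 0 with estimated correlations (smallest unadjusted p 0.0512) and 0 by fry (9 at an unadjusted p under 0.05). Among those 9 fry lists, only p53 targets, ERK feedback genes and YAP/TAZ targets were also called by camera. The fry p was 0.108 for immediate-early genes and 0.0888 for the respiratory chain. The smallest fry p was 0.00227 (adjusted p = 0.0840) for kidney progenitor genes, which camera did not call.

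Some values of genes that had not passed, and of GAS1, which had, changed sign. AMER1 was 0.33 in F18 alone and -1.24 in F5 alone. The mitochondrial DNA genes COX2 and COX3 turned to 0.023 and 0.093 after quantile normalization and 0.16 and 0.059 after loess. On other probe sets, without _x_at and _s_at, IDI1 turned to -0.00554, KIF23 to -0.31, GAS1 to -0.99, RRP12 to 1.16 and CANX to 0.17. p53 targets, immediate-early genes, ERK feedback genes, YAP/TAZ targets and the respiratory chain kept their direction and their call under every setting of camera with the preset correlation. Errors grow toward low signals, and in simulated data with 2 arrays per group 31.3% of 1.5-fold changes were recovered.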

Other observations

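The test of gene families was chosen only after the data had been seen. Of 140 families of genes that share a symbol stem and have at least 10 tested members, camera called 13 with doxycycline. The smallest adjusted p was 0.956 with estimated correlations, a variant that rests on 1 residual degree of freedom and has little power. KLF transcription factors were higher, with a median of 0.41 over 13 genes (0.63 in F5 and 0.33 in F18, adjusted p = 0.00882), and 9 were higher in both clones. KLF6 (0.69 ± 0.18) and KLF11 (0.87 ± 0.21) were called singly. KLHL genes, many of them adaptors of cullin ubiquitin ligases, had a median of 0.20 over 27 (adjusted p = 0.0106), and DNAJB cochaperones 0.25 over 10 (adjusted p = 0.0281). These 3 families kept their direction and their call after quantile normalization, cyclic loess and centring, but the DNAJB median lay inside the range of 2000 brightness-matched lists (upper end 0.25).

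The complex I families NDUFA (median -0.42 over 12, adjusted p = 1.45e-08) and NDUFB (-0.42 over 11, adjusted p = 4.71e-08) were lower in both clones in all 12 and all 11 members. They overlap with the respiratory chain list, which also holds genes of the COX and ATP stems, such as COX7A2 and ATP5MC1. The COX family (median -0.22, 6 of 26 genes called lower) and the mitochondrial ribosomal MRPL family (median -0.16, 2 of 49 called lower) stayed called as families under the 3 other scalings. Of the MRPL genes, 22 were lower and 5 higher in both clones. The mitochondrial translation list fixed beforehand did not pass, with 0 of 29 genes called (median -0.07, camera adjusted p = 0.0787), and the COX median lay inside the range of brightness-matched lists (lower end -0.24). MRPS (-0.14), ATP (-0.14), EMC (-0.24) and EIF (-0.10) families kept their direction but lost the call after loess and after quantile normalization. The ATP family is the 70 tested genes of that symbol stem, not a list of ATP synthase subunits. Ribosomal RPL and RPS genes had medians of -0.24 and -0.24, which turned to 0.02 and 0.04 after cyclic loess. The medians of RPL, MRPS and EIF genes also lay inside the ranges of brightness-matched lists.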
